A study of Homo sapiens with 10 samples.

How the data were processed

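Bulk RNA sequencing of CH157-MN, an established human meningioma cell line, was available for 10 libraries in 2 groups of 5. The PBS group received phosphate-buffered saline. The ADC group received 100 nM of a humanised antibody-drug conjugate that carries monomethyl auristatin F (MMAF), an inhibitor of tubulin polymerisation, on an antibody against the somatostatin receptor SSTR2, and was harvested 3 days later, per the labels. The labels give the day of harvest for the treated cells alone. Per the labels' protocols, messenger RNA was selected on poly-T beads, fragmented and reverse transcribed with random hexamers, and sequenced on an Illumina instrument. That protocol leaves open whether the libraries keep the strand.

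The deposited table holds whole-number counts per gene, not normalised, for 58735 genes with their Ensembl identifiers, symbols, positions and biotypes. The submitters' processing notes name HISAT2, HISAT and TopHat2 without a role and the genome build hg38. The counting tool, its strand setting and the annotation release are not given in the sources used here. All 58735 identifiers were found in GENCODE release 29 (Ensembl 94), with the same start and end for 58724 of them, so exon overlap, transcript length and GC content were taken from that release. Counts from 2 to 21 were even in 65.4% to 67.3% of cases in every library, against 49.0% to 50.6% of counts of 1000 or more. Counts may therefore hold both mates of a read pair, and 2 counts can come from 1 fragment.

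Total counts ranged from 28262162 to 36463724 per library. At this depth 3 counts, the most that an observed 0 leaves open, correspond to 0.0823 to 0.106 CPM (counts scaled to the same total in every library). These limits take each count as a separate fragment and are too low where both mates of a pair were counted. Such limits cover counting error only. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 5.18 to 16.5 over genes with at least 20 counts in the pair), so no library was treated as a repeat of another. The labels do not say that the replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. No batch is given in the labels.

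Groups were taken from the treatment labels. Counts were scaled with TMM factors, which ranged from 0.979 to 1.02, and genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 14504 genes. The comparison of ADC with PBS used edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from this test unless another tool is named. Each log2 fold change is ADC minus PBS. Its standard error (SE) was the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM with the SD over 5 libraries. The common coefficient of variation between libraries of a group, beyond counting noise, was 7.60%, and it may be biological or technical.

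Before the data were examined, 36 gene lists were fixed. The 32 lists with at least 5 tested members were compared with the other tested genes by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, two-sided, and adjusted over the 32 lists. The test was repeated with the correlation estimated from the data, and an adjusted p from that repeat is given beside each list whose call it ended. Members were also counted with p-values adjusted over the list alone.

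The genes named in the text were set by a rule fixed at the same time. It takes the 5 somatostatin receptor genes and, in each direction, the 10 protein-coding genes with the largest change among those called, with at least 5 CPM in the group where they were higher and no overlap between the groups. It adds the 3 members of each shifted list with the smallest adjusted p, the leading member of the opposite direction, and 20 genes named in advance. Where a list had 5 or fewer called members in a direction, these are also named, and they were chosen after their values were seen. Some genes that the rule names are not reported here.

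The tests were checked on simulated counts for the 14504 genes of the comparison of ADC with PBS, in 5 simulations of 200 changed genes each. The edgeR test recovered 48.8% of genes changed 1.2-fold, 74.9% of those changed 1.5-fold and 85.9% of those changed 2-fold, and 5.11% of its calls were false. Lists of 30 genes shifted by 0.3 on the log2 scale were called in 5 of 5 simulations and lists with no shift in 0 of 500. Smaller shifts, as most of the reported lists have, were not simulated. Each gene was simulated independently and the lists were drawn at random. The false calls of lists whose members vary together were therefore not tested. For DESeq2 9.64% of calls were false and for limma-voom 4.22%. Each simulation held the 200 changed genes and 1 shifted list of 30, far fewer than the 3018 genes called in the data. The Benjamini-Hochberg cut-off depends on how many genes change. The recovered and false shares are therefore not those of the real comparison.

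Alternatives fixed with the lists were DESeq2 1.42.0, limma-voom, RLE size factors, scaling to library size alone, no filter on low counts, a filter at a mean of 1 CPM, the replicate number as a block, leaving out each library in turn, protein-coding genes only, and 3 other settings of the list test. A correction for GC content and transcript length and a repeat with halved counts were added after the data had been seen. Figures were drawn with matplotlib 3.10.9. No genome sequence was used.

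The strand setting of the counting is not stated, so reads of a gene cannot be told from those of a gene that overlaps it. Among the named genes, the share of exonic bases that overlap another gene on the same strand was 36.5% for HSPA1B, 35.8% for TUBB3, 20.2% for RRM2 and 13.9% for OSGIN1. Overlap on any strand was 39.6% for DDIT3, 36.6% for TUBA1B, 31.1% for PLAU, 26.5% for IER3, 25.0% for TUBA1C, 21.3% for IFITM3, 18.9% for HLA-B, 18.1% for TUBA4A, 17.7% for NQO1, 16.0% for TUBB and 15.9% for FOXM1. Values of these genes, and of families of near-identical genes (HSPA1A and HSPA1B, CGB8, the CXCL1 cluster, tubulins, histones and HLA genes), are uncertain to that extent.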

Results

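The transcriptome of CH157-MN meningioma cells was measured by poly(A) RNA sequencing in 5 libraries from cells given PBS and 5 libraries from cells given 100 nM of a humanised SSTR2 antibody-drug conjugate loaded with the tubulin inhibitor MMAF, harvested 3 days after treatment. Deposited counts summed to between 28262162 and 34473795 per PBS library and between 28638057 and 36463724 per ADC library, and 19109 to 20035 genes had a count. Mitochondrial transcripts took 1.19% to 2.63% of counts in PBS libraries and 1.30% to 2.11% in ADC libraries. The leading principal component of log2 CPM held 23.5% of the variance and separated the groups, with scores of -25.9 to -15.0 for PBS and 14.7 to 27.4 for ADC.

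The design holds a single comparison, which asks how the transcriptome of the tumour cells differed after exposure to the conjugate. Of 30 NF-kB and cytokine genes 25 rose after ADC (adjusted p = 0.0019 with an estimated correlation). Of 20 heat shock genes 13 fell and of 59 DNA replication genes 29 fell (each list at adjusted p = 0.056 with an estimated correlation, which ended its call). The cytokine IL1B rose by 2.63 on the log2 scale (SE 0.13, adjusted p = 9.1e-16), from 4.34 ± 0.63 CPM to 26.9 ± 6.5 CPM (SD, n = 5 per group). LAMA5, a laminin chain of basement membranes, rose by 2.13 (SE 0.13, adjusted p = 2.2e-13), from 3.89 ± 0.69 to 17.1 ± 3.6 CPM. TXNIP, an inhibitor of thioredoxin, fell by 1.26 (SE 0.09, adjusted p = 3.2e-12), from 20.2 ± 0.8 to 8.44 ± 0.99 CPM. The marker of proliferation MKI67 and the topoisomerase TOP2A did not pass the test, with log2 fold changes of -0.04 (SE 0.05) and -0.00 (SE 0.03).

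Of 14504 genes tested, 3018 were called, 1562 higher and 1456 lower. Most changes were small, with a median of 1.17-fold among called genes, and 170 genes changed at least 2-fold, 135 higher and 35 lower, the latter 21 without PBS replicate 1. Of the 170, 100 of the higher and 30 of the lower genes stayed under 5 CPM in both groups. Scaled to library size alone, 1835 genes were higher and 1063 lower, so the share of higher calls was 63.3% instead of 51.8%. The values of the groups did not overlap for 2066 genes, or 14.2% of those tested, where chance gives 0.794%.

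**Figure D1:**
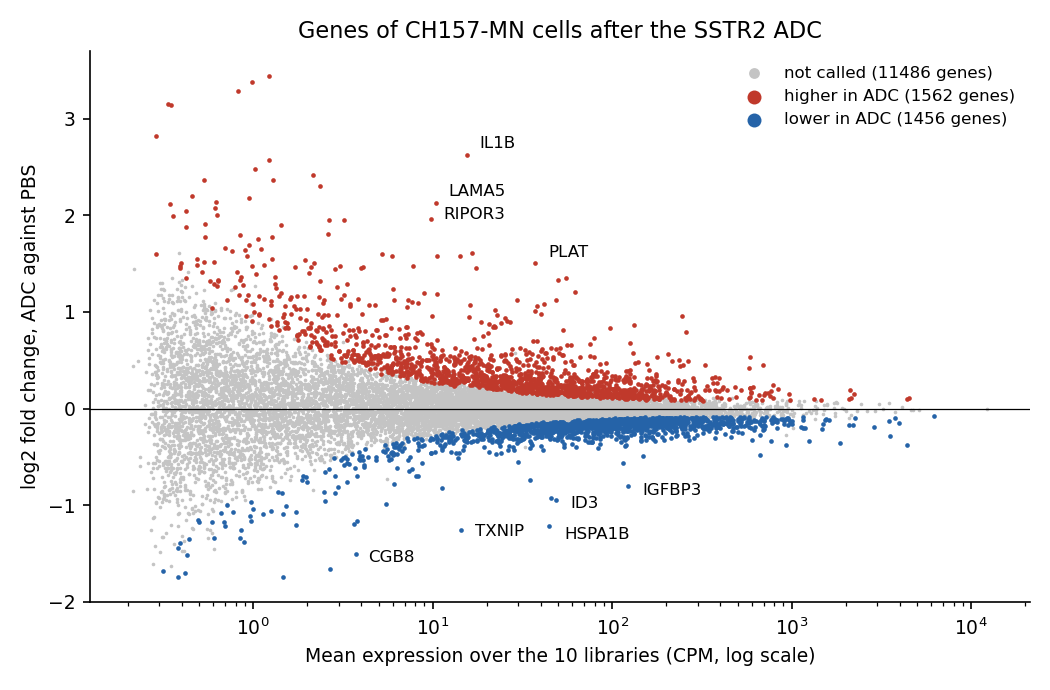
Log2 fold change of ADC against PBS (vertical axis) against mean expression in CPM on a log scale (horizontal axis), with 1 point for each of 14504 genes and labels on some of the genes with the largest changes. The 1562 genes called higher (red) reach larger fold changes than the 1456 called lower (blue), and 135 against 35 changed at least 2-fold.

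The other large increases by the fixed rule were RIPOR3 (log2 fold change 1.96, SE 0.11), C1QTNF1 (1.95, SE 0.21), the RAS-related GTPase gene RRAD (1.61, SE 0.10), the cholesterol exporter ABCA1 (1.6, SE 0.14), the junction protein plakoglobin gene JUP (1.58, SE 0.12), COLEC12 (1.58, SE 0.14), CD248 (1.58, SE 0.13) and the plasminogen activator PLAT (1.5, SE 0.07). Their adjusted p ranged up to 4.2e-08, the value of C1QTNF1. The other large decreases were the chorionic gonadotropin gene CGB8 (-1.50, SE 0.16), HSPA1B (-1.22, SE 0.06), LCP1 (-1.19, SE 0.19), the inhibitors of differentiation ID3 (-0.95, SE 0.05) and ID1 (-0.74, SE 0.06), HSPA1A (-0.92, SE 0.05), IGFBP3 (-0.81, SE 0.04), OSGIN1 (-0.70, SE 0.12) and PANX2 (-0.70, SE 0.11), with adjusted p up to 5.0e-05, the value of OSGIN1. The rule itself required that every ADC value of these genes lie outside the PBS values. CGB8 and the HSPA1A and HSPA1B pair have near-identical copies, so their own values are uncertain.

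On hg38, IL1B (ENSG00000125538) lies on chromosome 2 from 112829751 to 112836903, LAMA5 (ENSG00000130702) on chromosome 20 from 62307955 to 62367312, TXNIP (ENSG00000265972) on chromosome 1 from 145992435 to 145996600, and SSTR2 (ENSG00000180616) on chromosome 17 from 73165012 to 73176633. Counts were summed over whole genes, so no exon or UTR is singled out.

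The NF-kB and cytokine list, which holds genes that the transcription factor NF-kB activates, moved furthest. Of 30 tested members 25 rose, 0 fell and 5 were not called (CCL20, TRAF1, IL32, NFKB1 and NFKBIE), and 25 rose when adjusted over the list alone. The median log2 fold change was 0.68 (camera adjusted p = 7.6e-31), and the list was the only one still called with an estimated correlation, at adjusted p = 0.0019. The neutrophil-attracting chemokine CXCL8 rose by 1.35 (SE 0.06, adjusted p = 9.3e-17), from 31.3 ± 3.1 to 79.8 ± 4.9 CPM, and CXCL1 rose by 0.95 (SE 0.04, adjusted p = 4.2e-18), from 168 ± 7 to 325 ± 16 CPM. CXCL1 has close paralogs in its cluster, with which reads can be shared. Beside these increases, 19 leukocyte markers summed to 1.66 ± 0.88 CPM in PBS and 2.61 ± 0.37 CPM in ADC libraries (SD, n = 5).

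**Figure D2:**
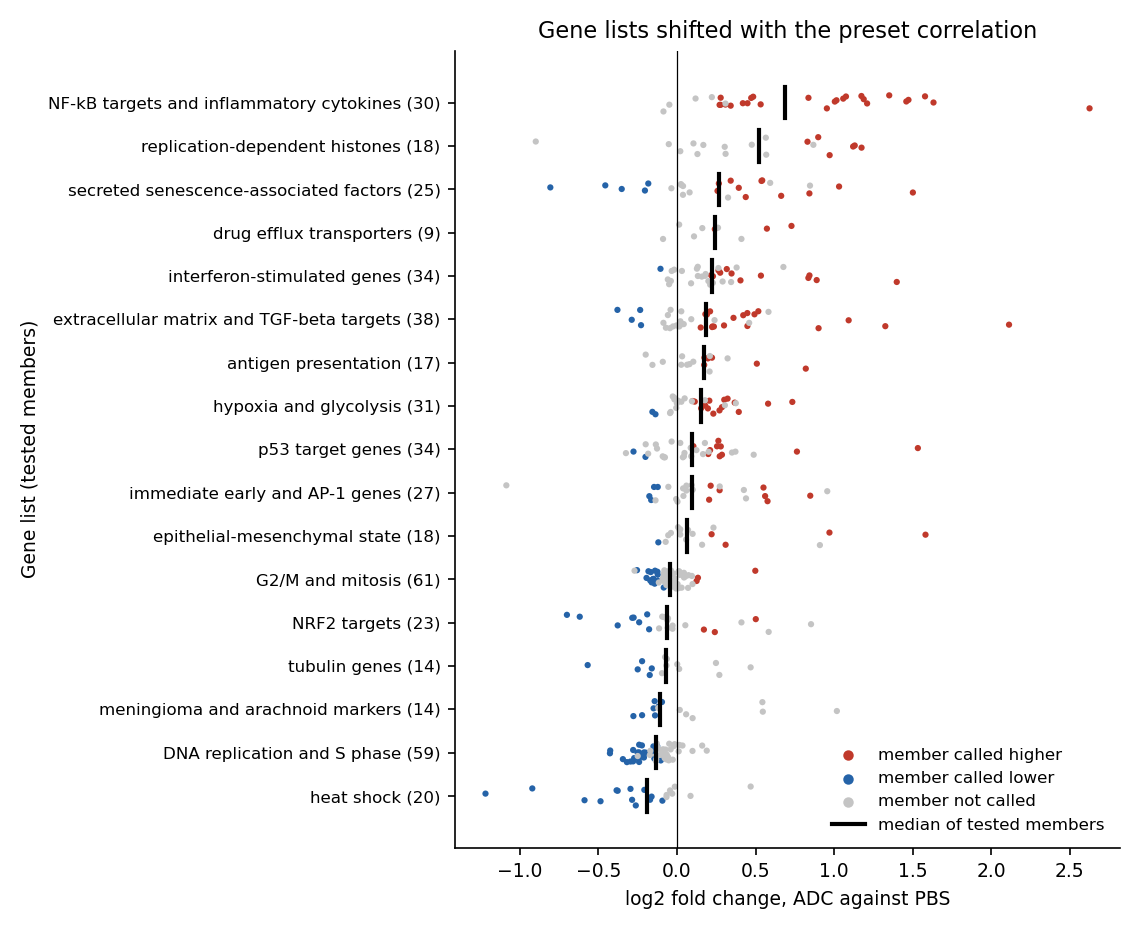
Log2 fold change of ADC against PBS (horizontal axis) for the tested members of the 17 lists shifted with the preset correlation (vertical axis, number of tested members in brackets). Points are genes, called higher (red), called lower (blue) or not called (grey), and black bars are list medians, from 0.68 for the cytokine list to -0.19 for heat shock.

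Of 38 extracellular matrix and TGF-beta target genes, 18 rose, 4 fell and 16 were not called, with the same counts adjusted over the list alone. The median was 0.19 (camera adjusted p = 3.4e-05), and the call was lost at adjusted p = 0.15 with an estimated correlation. COL1A2, a chain of type I collagen, rose by 1.33 (SE 0.07, adjusted p = 1.5e-14), from 28.5 ± 2.5 to 71.4 ± 10.4 CPM, and tenascin C (TNC) rose by 0.49 (SE 0.04, adjusted p = 8.1e-12). The members that fell were THBS1 (-0.38, SE 0.03), COL12A1 (-0.29), THBS2 (-0.23) and SMAD7 (-0.23).

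Among 25 secreted senescence-associated factors, 11 rose, 5 fell and 9 were not called, or 12 and 5 adjusted over the list alone. The median was 0.27 (camera adjusted p = 0.00085, and adjusted p = 0.098 with an estimated correlation). The plasminogen activators PLAT and PLAU rose, by 1.5 (SE 0.07) and 0.54 (SE 0.03). Among the members that fell were IGFBP3 (-0.81, SE 0.04), ANGPT1 (-0.46), FGF2 (-0.20) and the lamin gene LMNB1 (-0.18).

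Heat shock genes, which encode chaperones, were lower after ADC. Of 20 tested members 0 rose, 13 fell and 7 were not called, with the same counts adjusted over the list alone. The median was -0.19 (camera adjusted p = 1.7e-13), with adjusted p = 0.056 with an estimated correlation. HSP90AA1 fell by 0.38 (SE 0.03, adjusted p = 6.4e-12), from 4935 ± 27 to 3799 ± 173 CPM. HSPA1B fell from 62.5 ± 3.7 to 26.9 ± 2.7 CPM and HSPA1A from 59.9 ± 1.6 to 31.7 ± 2.1 CPM.

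Of 23 targets of NRF2, the regulator of the antioxidant response, 3 rose, 8 fell and 12 were not called, or 4 and 9 adjusted over the list alone. The median was -0.06 (camera adjusted p = 0.018, and adjusted p = 0.26 with an estimated correlation). GCLM, a subunit of the enzyme that limits glutathione synthesis, fell by 0.38 (SE 0.04, adjusted p = 3.2e-08), and NQO1 fell by 0.24 (SE 0.04, adjusted p = 6.4e-06). AKR1B1 rose by 0.50 (SE 0.04, adjusted p = 2.0e-10), and ABCC1 (0.24) and HMOX1 (0.17) also rose.

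**Figure D3:**
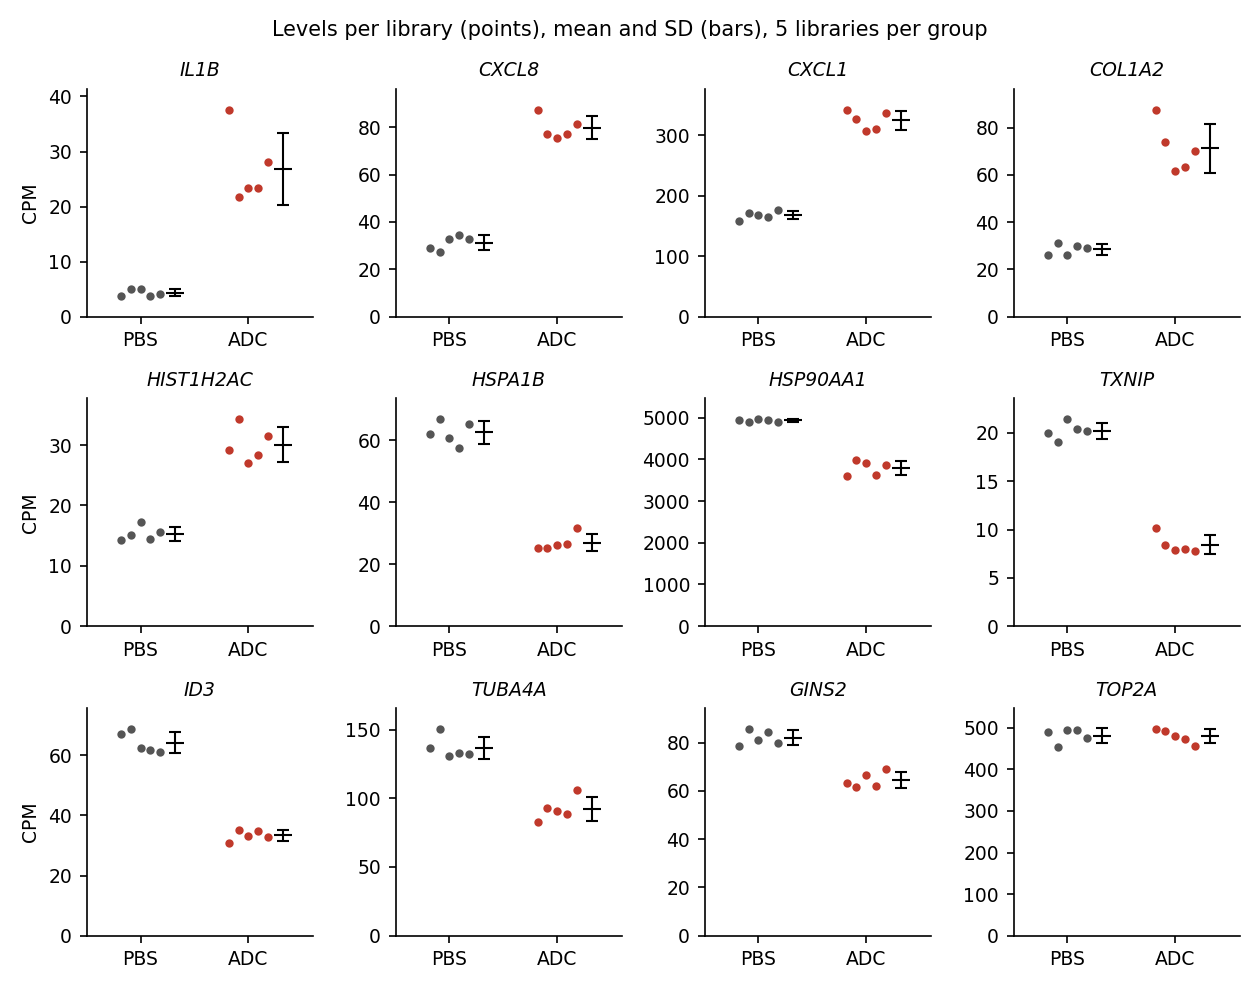
Expression in CPM (vertical axes, starting at 0) of 12 genes in each of the 5 PBS (grey) and 5 ADC (red) libraries, with the mean and SD as black bars. IL1B averaged 4.34 CPM in PBS and 26.9 CPM in ADC libraries, while TOP2A averaged 482 and 480 CPM.

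Genes of DNA replication and S phase were lower after ADC by small amounts. Of 59 tested members 0 rose, 29 fell and 30 were not called, or 3 and 38 adjusted over the list alone. The median was -0.13 (camera adjusted p = 1.7e-12, and adjusted p = 0.056 with an estimated correlation). GINS2, part of the replicative helicase, fell by 0.34 (SE 0.04, adjusted p = 7.4e-07), DSCC1 by 0.43 (SE 0.06, adjusted p = 2.4e-06) and the ribonucleotide reductase subunit RRM2 by 0.27 (SE 0.03, adjusted p = 2.5e-07). RRM2 shares 20.2% of its exonic bases with another gene on its strand.

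Of 61 G2/M and mitosis genes, 3 rose, 14 fell and 44 were not called, or 3 and 16 adjusted over the list alone. The median was -0.04 (camera adjusted p = 0.018, and adjusted p = 0.31 with an estimated correlation), and the call also ended without ADC replicate 4, at adjusted p = 0.083, and with GC and length trends removed, at adjusted p = 0.082. The mitotic kinase AURKB fell by 0.19 (SE 0.04, adjusted p = 0.00056) and CDC20 by 0.16 (SE 0.03, adjusted p = 0.00062). The kinetochore motor CENPE rose by 0.50 (SE 0.07, adjusted p = 8.5e-06), as did CKAP2L (0.12) and KIF20B (0.13). The mitotic cyclin gene CCNB1 was not called (0.04, SE 0.04, adjusted p = 0.41).

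Of 18 replication-dependent histone genes, 6 rose, 0 fell and 12 were not called, with the same counts adjusted over the list alone. The median was 0.52 (camera adjusted p = 8.9e-05, and adjusted p = 0.056 with an estimated correlation). HIST1H2AC rose by 0.97 (SE 0.08, adjusted p = 3.4e-11), from 15.3 ± 1.2 to 30.1 ± 2.9 CPM, HIST1H2BD by 1.12 (SE 0.12) and HIST1H2BK by 0.90 (SE 0.08). Most histone mRNAs end in a stem-loop and lack a poly(A) tail, so poly(A) libraries measure the polyadenylated part, and family members are similar in sequence.

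Of 34 p53 target genes, 10 rose, 2 fell (ZMAT3, -0.20, and SERTAD1, -0.28) and 22 were not called, or 16 and 3 adjusted over the list alone. The median was 0.10 (camera adjusted p = 0.012, and adjusted p = 0.056 with an estimated correlation). The cell cycle inhibitor CDKN1A rose by 0.21 (SE 0.05, adjusted p = 0.0057), the stress cytokine GDF15 by 1.53 (SE 0.31, adjusted p = 0.00055), from 0.995 ± 0.677 to 2.92 ± 0.63 CPM, and PLK2 and GADD45A by 0.28 (SE 0.03) and 0.29 (SE 0.04). The ubiquitin ligase gene MDM2 was not called (-0.08, SE 0.05, adjusted p = 0.22). The call of ZMAT3 was lost without PBS replicate 1, PBS replicate 3 or ADC replicate 5, at adjusted p of 0.050 to 0.072.

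Tubulin genes encode the subunits of microtubules, the structure that the payload targets. Of 14 tested members 0 rose, 5 fell and 9 were not called, or 1 and 7 adjusted over the list alone. The median was -0.07 (camera adjusted p = 0.0024, and adjusted p = 0.25 with an estimated correlation). TUBA4A fell by 0.57 (SE 0.05, adjusted p = 4.7e-10), from 137 ± 8 to 92.3 ± 8.8 CPM, TUBA1C by 0.25 (SE 0.04), TUBA1B by 0.22 (SE 0.04), TUBB by 0.17 (SE 0.03, adjusted p = 4.1e-05) and TUBB4B by 0.16. TUBB3 was near the detection limit at 0.436 ± 0.288 and 0.610 ± 0.329 CPM and was not called (adjusted p = 0.55). Tubulin genes are close paralogs, and 36.6% of the exonic bases of TUBA1B overlap a gene on the other strand.

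Of 9 drug efflux transporter genes, ABCA2 (0.73, SE 0.11), ABCA3 (0.57, SE 0.05) and ABCC1 (0.24, SE 0.05) rose, 0 fell and 6 were not called, with the same counts adjusted over the list alone. The median was 0.24 (camera adjusted p = 0.0037, and adjusted p = 0.056 with an estimated correlation). ABCB1, the gene of P-glycoprotein, had 0 to 8 counts per library and was not tested.

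Of 34 interferon-stimulated genes, 12 rose, 1 fell and 21 were not called, or 15 and 1 adjusted over the list alone. The median was 0.22 (camera adjusted p = 5.8e-05, and adjusted p = 0.056 with an estimated correlation). The antiviral gene IFITM3 rose by 0.32 (SE 0.04, adjusted p = 1.2e-06), LGALS3BP by 0.23 (SE 0.03), OASL by 1.40 (SE 0.25, adjusted p = 9.2e-05) and IFIT1 by 0.84 (SE 0.24, adjusted p = 0.013), the last from 1.45 ± 0.49 to 2.59 ± 0.59 CPM. The call of IFIT1 was lost without ADC replicate 2, at adjusted p = 0.057. ISG15 was not called (0.23, SE 0.09, adjusted p = 0.078), but it passed without PBS replicate 5 (adjusted p = 0.033) and without ADC replicate 3 (adjusted p = 0.046).

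Of 17 antigen presentation genes, 6 rose, 0 fell and 11 were not called, or 7 and 0 adjusted over the list alone. The median was 0.17 (camera adjusted p = 0.010, and adjusted p = 0.056 with an estimated correlation). The immunoproteasome subunit PSMB9 rose by 0.82 (SE 0.12, adjusted p = 5.1e-06), and the class I genes HLA-B and HLA-E rose by 0.22 (SE 0.05) and 0.17 (SE 0.04). B2M, calreticulin (CALR) and HMGB1 were not called, with log2 fold changes of 0.08 (SE 0.03), 0.08 (SE 0.03) and -0.01 (SE 0.03), but B2M and CALR passed without PBS replicate 2, ADC replicate 1 or ADC replicate 4, at adjusted p of 0.013 to 0.046. They also passed with DESeq2 (adjusted p = 0.011 and 0.026), limma-voom (0.034 and 0.027), library size alone (0.0086 and 0.0074), a mean of at least 1 CPM (0.033 and 0.039), the replicate number as a block (0.043 and 0.032) and GC and length trends removed (0.0023 and 0.022), and B2M with halved counts (0.043). CD274, which encodes the checkpoint ligand PD-L1, fell by 0.33 (SE 0.05, adjusted p = 8.3e-06), from 55.0 ± 2.1 to 43.9 ± 1.6 CPM. The checkpoint list itself was not shifted (camera adjusted p = 0.88), and of its 19 tested members CD47, NECTIN2, NT5E and VSIR rose and ULBP3, CD274, MICB and PVR fell.

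Of 31 hypoxia and glycolysis genes, 15 rose, 2 fell (HK2, -0.14, and PFKM, -0.16) and 14 were not called, or 16 and 2 adjusted over the list alone. The median was 0.15 (camera adjusted p = 3.7e-05, and adjusted p = 0.14 with an estimated correlation). NDRG1 rose by 0.58 (SE 0.06), the angiogenic factor VEGFA by 0.39 (SE 0.04, adjusted p = 8.2e-08) and the neuronal enolase ENO2 by 0.29 (SE 0.05).

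Of 27 immediate early and AP-1 genes, 7 rose, 4 fell and 16 were not called, or 7 and 5 adjusted over the list alone. EGR1 rose by 0.85 (SE 0.08, adjusted p = 9.3e-10), IER3 by 0.58 (SE 0.04) and JUND by 0.56 (SE 0.06), while JUN (-0.16, SE 0.03), DUSP5 (-0.18), FOSL1 (-0.15) and MYC (-0.12) fell. Of 18 genes of the epithelial-mesenchymal state, JUP, KRT7 (0.97), ZEB2 (0.31, SE 0.05) and TWIST2 (0.22, SE 0.06) rose, N-cadherin (CDH2, -0.12, SE 0.04) fell and 13 were not called, or 5 and 1 adjusted over the list alone. JUP and KRT7 are epithelial genes, and ZEB2 and TWIST2 encode mesenchymal transcription factors. Both lists passed narrowly at camera adjusted p = 0.0498, with medians of 0.09 and 0.06. With an estimated correlation the calls were lost, at adjusted p = 0.25 for the AP-1 list and adjusted p = 0.12 for the epithelial-mesenchymal list. Each call was also lost without any of 4 single libraries, PBS replicates 1 and 3 and ADC replicates 4 and 5 for the AP-1 list (adjusted p of 0.0643 to 0.0812) and PBS replicates 1 and 3 and ADC replicates 2 and 3 for the other (adjusted p of 0.0511 to 0.0682), and CDH2 lost its call without PBS replicate 1 (adjusted p = 0.053).

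Of 14 meningioma and arachnoid markers, 0 rose, 7 fell and 7 were not called, or 3 and 8 adjusted over the list alone. The median was -0.11 and the test pointed down (camera adjusted p = 0.018, and adjusted p = 0.14 with an estimated correlation), while the mean was 0.07. Without PBS replicate 5 the call ended at adjusted p = 0.052. The leading members that fell, HMGA2 (-0.28, SE 0.03, adjusted p = 3.2e-08), MYBL2 (-0.22, SE 0.03) and FOXM1 (-0.14, SE 0.03), are genes of proliferating tumour cells and not markers of arachnoid identity.

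SSTR2, the target of the antibody, had 3 to 22 counts per PBS library and 10 to 20 counts per ADC library, or 0.297 ± 0.263 and 0.430 ± 0.103 CPM (SD, n = 5). The difference was not detectable at this depth (log2 fold change 0.54, SE 0.50, adjusted p = 0.50). Without PBS replicate 3, the library with 22 counts, the log2 fold change was 1.21 at adjusted p = 0.12. SSTR1 had 17 to 33 counts in PBS and 11 to 31 in ADC libraries and was not called (-0.22, SE 0.39, adjusted p = 0.74). SSTR3 had 0 to 4 counts in PBS and 0 in ADC libraries, and SSTR4 and SSTR5 had 0 in all 10. In the shallowest library taken alone, 0 counts allow about 0.106 CPM if every count is a separate fragment. The limit is higher if both mates of a pair were counted, and lower over all 10 libraries together.

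**Figure D4:**
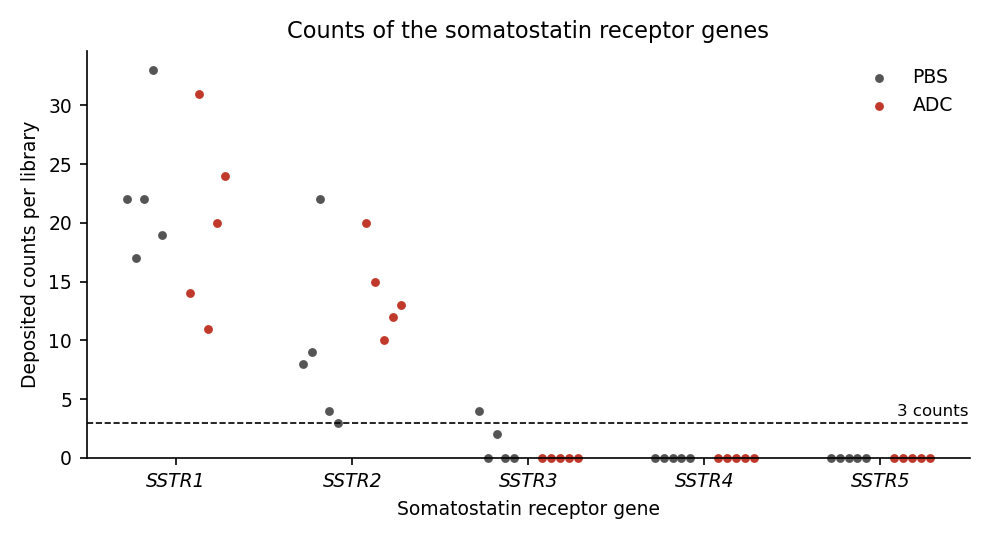
Deposited counts (vertical axis) of the 5 somatostatin receptor genes (horizontal axis) in each PBS (grey) and ADC (red) library, with a dashed line at 3 counts. SSTR2 lies between 3 and 22 counts in all 10 libraries, and SSTR4 and SSTR5 lie at 0.

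The other 14 tested lists were not shifted. The SRF and YAP target list had 8 members higher and 7 lower of 34 (11 and 8 adjusted over the list alone, camera adjusted p = 0.78), and its member CCN2, named CTGF in the table, rose by 0.20 (SE 0.03, adjusted p = 4.5e-05). Lysosome genes had 7 higher and 8 lower of 40 (8 and 8, adjusted p = 0.89), endocytic genes 7 and 4 of 31 (7 and 4, adjusted p = 0.30) and microtubule-associated and kinesin genes 6 and 3 of 37 (8 and 3, adjusted p = 0.08). Genes of the integrated stress response had 6 and 6 of 31 (9 and 7, adjusted p = 0.89), and its death-linked factor DDIT3 was not called (0.19, SE 0.13). In the unfolded protein response list HSPA5 and HSP90B1 rose and DNAJC3 and CANX fell, of 26 (2 and 2, adjusted p = 0.099). For autophagy WIPI1, OPTN, GABARAPL1 and ULK1 rose and ATG3 fell, of 31 (4 and 1, adjusted p = 0.055). In cholesterol synthesis LSS rose and 5 fell, among them DHCR7, FDPS, SC5D and ACAT2, of 24 (2 and 5, adjusted p = 0.30). Among apoptosis genes BMF, ENDOG and CASP9 rose and BIRC2, CYCS, CASP2, BAK1 and BIRC3 fell, of 31 (3 and 5, adjusted p = 0.89).

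In cytosolic DNA sensing STING (TMEM173) and IFI16 rose and CGAS and TRIM56 fell, of 9 (2 and 2 adjusted over the list alone, camera adjusted p = 0.78). Of 45 nuclear-encoded oxidative phosphorylation genes 6 rose and 0 fell (5 and 0, adjusted p = 0.19). RPL3 and RPL10 rose and 0 fell of 53 ribosomal protein genes (1 and 0, adjusted p = 0.32). MT-ND3 fell and 0 rose of 13 mitochondrially encoded mRNAs (0 and 0, adjusted p = 0.67). With 1 library left out, ribosomal protein genes passed without PBS replicate 2 (adjusted p = 0.0018) and ADC replicate 1 (adjusted p = 0.028), and oxidative phosphorylation genes without the same libraries (adjusted p = 0.027 and 0.028). Mitochondrially encoded mRNAs passed without PBS replicate 4 (adjusted p = 0.046), autophagy genes without PBS replicate 2, PBS replicate 3 or ADC replicate 3 (adjusted p of 0.035 to 0.047), and microtubule-associated genes without ADC replicate 5 (adjusted p = 0.047). For apoptosis the median was 0.01 while the test pointed down, for DNA sensing the median was -0.04 while the test pointed up, and for the integrated stress response the mean was 0.06 while the median was -0.02.

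Some markers of other cell types moved with the treatment. Endothelial markers summed to 11.2 ± 0.5 CPM in PBS and 13.8 ± 0.8 CPM in ADC libraries (SD, n = 5), and of 5 tested PECAM1 rose by 1.77 (1 and 0 adjusted over the list alone, camera adjusted p = 0.20). Lists with fewer than 5 tested members were not tested as a group. Neural and glial markers summed to 84.7 ± 5.6 and 93.4 ± 1.7 CPM, and SNAP25 (0.85), SYT1 (0.73) and SLC1A3 (0.31) rose of 4 tested, 3 and 0 adjusted over the list alone. Epithelial carcinoma markers summed to 0.946 ± 0.321 and 1.40 ± 0.28 CPM, and of 2 tested SYP (1.88) rose, 1 and 0 adjusted over the list alone. SYP encodes synaptophysin, a protein of synaptic vesicles and neuroendocrine cells and not an epithelial protein, and the epithelial marker CLDN4 was not called (0.16, SE 0.49). The only leukocyte marker tested, CSF1R, was not called over all genes (0.72, 1 and 0 adjusted over the list alone), and of the somatostatin receptors and ligands 2 were tested and 0 called, also when adjusted over the list alone.

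With the preset correlation 17 of the 32 lists were shifted, 11 up and 6 down, and with an estimated correlation 1 was. The ADC group differs from PBS in the antibody and in its payload together, and no group with the unconjugated antibody was analysed here. The labels give the day of harvest for the ADC group alone, so a difference in time of harvest cannot be told apart from the treatment.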

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

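The tests of leukocyte markers, of G2/M against replication genes and of the overlap of SSTR2 with other genes, and the correction for GC content and length, were chosen only after the results had been seen.

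NF-kB and cytokine genes were higher after ADC, with 25 of 30 members called. Removing the trends with GC content and transcript length in each library, which moved the log2 fold changes of all genes with an SD of 0.026, left the list median at 0.69 (bootstrap 95% interval over members 0.36 to 1.07) against 0.68 before, which argues against such a bias as the whole cause. Leukocytes in the ADC cultures are also argued against as the source of the summed rise of the list. The 19 leukocyte markers rose by 0.142% of the 666.6 CPM by which the cytokine list rose (0.427% with 2 SD added). Of these markers, 16 stayed under 10 counts in every library. Abundant members such as CXCL1 weigh most in that sum, and the markers themselves went from 1.66 to 2.61 CPM. The ratio therefore does not decide the question for members of low expression. A response of the tumour cells to the treatment remains as a hypothesis. Whether the antibody, MMAF or another component of the preparation would be responsible stays open, since the ADC group received all of them together.

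After ADC 29 of 59 DNA replication genes were called lower and 6 of 18 histone genes higher, and each list lost its call at adjusted p = 0.056 with an estimated correlation. With GC and length trends removed the medians were -0.14 for replication (95% interval -0.16 to -0.11, against -0.13 before) and 0.49 for histones (0.10 to 0.82, against 0.52 before), and 32 and 6 members were called, so this bias is argued against as the whole cause of either. The G2/M median lay above the replication median by 0.091 (bootstrap 95% interval over members 0.056 to 0.13). A two-sided permutation over genes gave p = 2e-05 (100000 permutations). An equal fall of all cycling cells as the only change would give no such gap. Genes are not independent replicates, both medians were known before the test was chosen, and neither list was called with an estimated correlation. The gap therefore does not decide on that explanation, alone or together with another change. A change in the phases of the cycle after the tubulin inhibitor, and a change in the share of histone mRNA that carries a poly(A) tail, may each contribute and were not tested.

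SSTR2 transcripts lay near the detection limit in all 10 libraries, at 3 to 22 counts. Loss of reads to overlapping genes is argued against, since 3.53% of its exonic bases are shared with another gene. Incomplete transcript models and the unstated counting rules stay open as technical causes. No biological explanation was tested, since all libraries come from the same cell line and no receptor measurement was analysed here.

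Chance division of the libraries is argued against for the counts of genes. Every other split mixes PBS and ADC libraries, which adds the treatment difference to the spread within groups and lowers its calls. The splits cannot tell the treatment from another difference between the groups. Among 100 of the 126 ways to split the 10 libraries into 5 and 5, the real split called 3018 genes and the highest of the others 2, and for changes of at least 2-fold the values were 170 and 0, so in both cases 1 split of 100, the real one, reached the real count. For the gene lists 1 split of 100 likewise reached the real count of 17, and the highest of the others gave 16 with a median of 6. The split with 16 lists keeps 4 libraries of a group together and so carries part of the treatment difference. The 21 splits of this kind had a median of 13 lists, and the 78 splits that keep 3 together had a median of 4.5 and at most 13. With an estimated correlation the real split called 1 list and the others 0. The median of 15 of the 32 lists was further from 0 in the real split than in any other drawn. The 15 include unfolded protein response and autophagy genes, which were not called. Some margins were thin, as for p53 target genes, at 0.0976 against a highest absolute value of 0.0949 in the others. Of the lists reported as shifted this did not hold for tubulin (16 of 100 splits as large, the real one included), epithelial-mesenchymal (10), NRF2 (8) and G2/M (3) genes.

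Within groups, 6 values out of 188 sets of 5 stood apart from the other 4 by a gap over 0.71 of the whole range, and chance gives about 1 in 20. In the PBS group replicate 2 had the highest RRAD (3.32 on the log2 CPM scale against 2.99 for the nearest library, gap 0.816) and the highest TWIST2 (4.85 against 4.66, gap 0.809). In the ADC group replicate 5 had the fewest genes with a count (19109 against 19772, gap 0.716), the lowest MDM2 (5.84 against 5.96, gap 0.772) and the highest HSPA1B (4.98 against 4.72, gap 0.79). ADC replicate 2 had the lowest ABCA1 (2.62 against 3.02, gap 0.821).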

How the results depend on the processing

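The correction for GC and length and the halved counts were chosen after seeing the data. The number of called genes stayed between 2491 (without ADC replicate 1) and 3404 (GC and length removed), and no gene called both in the reported fit and under an alternative changed sign. DESeq2 called 3362 genes, limma-voom 3003, protein-coding genes alone 3027. No pairing by number was detected: correlations of same-numbered libraries ran from -0.0264 to 0.0975, and 3 of 10 libraries correlated best with their own number. The highest correlation between libraries of different number was 0.291, for PBS replicate 2 and ADC replicate 5. These libraries also had the lowest scores on the second principal component, -22.3 and -26.0, which held 11.4% of the variance. The labels name no factor that they share, and such a factor was not tested. With the replicate number as a block, 3152 genes were called.

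The count of genes changed at least 2-fold rose from 170 to 261 with no filter on low counts and was 100 with a mean of at least 1 CPM, which tests fewer genes. The higher ones were 87 with the latter filter. The lower ones, 35 as reported, were 65 with no filter, 13 at 1 CPM, 22 with counts halved, and 21 to 39 with 1 library left out, the lowest without PBS replicate 1. Gene lists shifted numbered 1 with an estimated correlation and 12 on ranks. The fry test, which sets a list against no change and not against the other genes, called 22 lists. SSTR2 was not called in any fit that kept it, it was filtered out at 1 CPM and with halved counts, and DESeq2 gave it no adjusted p.

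The results that reversed under an alternative were not called as reported. TOP2A was 0.01813 with library size alone, 0.01623 with GC removed and -0.02436 to 0.01605 with 1 library left out. HMGB1 was 0.01002, 0.01323 and -0.02678 to 0.006209 in the same settings. MKI67 ran from -0.08174 to 0.01274 and SSTR1 from -0.3685 to 0.00634 with 1 library left out. Adjusted p of reversed lists were 0.95 for the integrated stress response with library size alone, 0.793 and 0.923 for apoptosis with no filter and on ranks, 0.971 for checkpoint genes at 1 CPM and 0.854 for SRF and YAP targets with GC removed. With 1 library left out, some fits of 5 lists reversed. Over all 10 fits, reversed or not, adjusted p ran from 0.806 to 0.972 for apoptosis and 0.798 to 0.971 for the integrated stress response. It ran from 0.675 to 0.972 for lysosome, 0.00175 (called without PBS replicate 2) to 0.983 for ribosomal and 0.0461 (called without PBS replicate 4) to 0.972 for mitochondrial genes. These calls kept the reported direction. The reversed fits gave 0.935 for apoptosis, 0.817 to 0.971 for the integrated stress response and 0.874 to 0.972 for lysosome genes. They gave 0.955 for ribosomal and 0.226 to 0.972 for mitochondrial genes. For the reversals the cause was not tested. Among named genes the calls of CDH2 (without PBS replicate 1, adjusted p = 0.053) and ZMAT3 (without PBS replicates 1 and 3 or ADC replicate 5, adjusted p of 0.050 to 0.072) were also lost. The list calls that other settings ended were G2/M (GC and length removed 0.0816), AP-1 (RLE 0.0508, block 0.0552, GC and length removed 0.0816, ranks 0.0828), epithelial-mesenchymal (RLE 0.0508, no filter 0.127, 1 CPM 0.0658, ranks 0.0828), meningioma (ranks 0.143), NRF2 (ranks 0.0543) and tubulin (ranks 0.0519). With library size alone CDH2 also lost its call (adjusted p = 0.0611), and 22 lists passed. Lists not called as reported that passed under these settings were autophagy (no filter 0.0193, 1 CPM 0.0451, library size alone 0.0284, GC and length removed 0.0472), unfolded protein response (no filter 0.0246, library size alone 0.0284), microtubule-associated genes (no filter 0.0352, library size alone 0.0471), ribosomal (library size alone 0.0156), oxidative phosphorylation (library size alone 0.0471) and endothelial (no filter 0.0254). With no filter 20 lists passed. With counts halved, 136 genes changed at least 2-fold.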

Other observations

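The genes named here and the test of tubulin classes were chosen only after the results had been seen. The transcription factor CEBPD rose by 1.45 on the log2 scale (SE 0.09, adjusted p = 2.7e-13), from 9.34 ± 0.62 to 25.6 ± 3.7 CPM (SD, n = 5), complement C3 by 0.98 (SE 0.06, adjusted p = 6.2e-13), from 27.1 ± 1.8 to 53.3 ± 5.3 CPM, and C1R by 1.32 (SE 0.22) and C1S by 1.11 (SE 0.32), both under 4 CPM. The metalloproteinase inhibitor TIMP3 rose by 0.79 (SE 0.04), from 189 ± 6 to 326 ± 18 CPM. The natural antagonist of interleukin 1, IL1RN, rose by 2.18 (SE 0.35, adjusted p = 3.0e-05), to 1.56 ± 0.36 CPM.

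The pro-apoptotic gene BMF rose by 2.30 (SE 0.24, adjusted p = 1.9e-08), from 0.789 ± 0.178 to 3.92 ± 1.11 CPM, although the apoptosis list did not shift. TMEM119 (3.44, SE 0.43) and DHRS3 (3.37, SE 0.45) had larger log2 fold changes than IL1B, at 2.24 ± 0.93 and 1.79 ± 0.65 CPM after ADC. RGPD5 fell (-1.16, SE 0.28) and its near-identical copy RGPD6 rose (1.90, SE 0.42), with reads that can be shared between them.

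As a hypothesis, tubulin mRNA autoregulation, in which free tubulin speeds the decay of alpha and beta tubulin mRNAs, may contribute to their lower levels. It would require that the inhibitor of polymerisation raises free tubulin in these cells, which was not measured here. The 10 tested alpha and beta genes had a median log2 fold change of -0.13, with 5 called lower, and the 4 gamma, delta and epsilon genes a median of 0.01 with 0 called. The difference of -0.14 had the sign predicted if free tubulin rises, but an exact permutation of the 2 classes over the 14 genes gave p = 0.206, two-sided. With 4 genes in the smaller class, autoregulation and chance cannot be told apart here.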
